A study of Mus musculus with 6 samples.

How the data were processed

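Chromatin accessibility was measured by ATAC-seq in 6 libraries from pro-B cell lines, cultured precursors of B lymphocytes from mouse bone marrow. The lines lack RAG2, a part of the recombinase that joins antigen receptor gene segments, so the IgH locus is not rearranged by it. WT is 1 line, and CBE_1 and CBE_2 are 2 lines whose IgH alleles carry a mutated IGCR1, a control region between the VH and D segments of the IgH (immunoglobulin heavy chain) locus whose elements bind the insulator protein CTCF. Each line has 2 libraries, made from 200000 cells each with 11 cycles of PCR, per the labels. Nothing in the labels says that the duplicates came from separate cultures, so differences between them may be technical. Replicates are numbered in accession order.

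For each library the authors deposited 1 peak list. Trimmomatic, Bowtie2, SAMtools and Picard and the mouse build mm9 are named in the submitters' processing notes, without versions. The peak caller and its settings, and whether reads were shifted for the position of the transposase, are not given in the sources used here. A shift moves peak edges by a few bases only and would act alike on all lists. The reads were not analysed here, so the number of mapped reads per library is unknown. Each list gives the peak's position, a score, a fold over background, −log10 of the p-value and of the q-value, and the summit position. The score, the fold (a ratio) and both −log10 columns are the authors' own values for a peak, and were used only to describe, rank or filter peaks within a list. The deposited score equals the whole part of 10 times the deposited −log10 q-value. All folds of a list were whole multiples of 1 step, within a tolerance of 2% of that step. Under a Poisson model in which a fold is a pileup count plus 1 over a background count plus 1, the step gave a background count of 8.24 and 8.10 in WT, 5.63 and 8.59 in CBE_1, and 7.16 and 8.31 in CBE_2. The deposited −log10 p-value lay within 1% of that model for 99.89% of peaks or more in every list. These backgrounds are inferred from the lists and are not read counts, so they do not give the depth of a library. The lowest was that of CBE_1 replicate 1 and the highest that of CBE_1 replicate 2.

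Peaks of the 6 lists were merged into regions where they overlapped by at least 1 bp, and a region was present in a library when 1 of its peaks fell in it. WT-only regions are present in both WT libraries and in none of the 4 mutated libraries, and IGCR1-mutated-only regions are the reverse. CBE_1-only and CBE_2-only regions are present in both libraries of that line and in none of the other 4. CBE_1-absent and CBE_2-absent regions are missing from both libraries of that line and present in the other 4. Counts were set against the same counts for all 15 choices of 2 of the 6 libraries, where the smallest share that the real choice can reach is 0.0667, so no such comparison can pass 0.05. The mutated genotype is compared with 1 WT line, so line and genotype cannot be told apart in any of these comparisons.

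Windows for the IgH locus on chromosome 12 and the Igk light chain locus on chromosome 6, a narrower IgH subwindow from the D, J and Cμ segments to the nearest VH segments, and a narrow IGCR1 window were set from general knowledge of mm9 before the data were examined, and their borders are approximate. Shares of regions inside a window were compared with the rest of the chromosome by two-sided Fisher exact tests with Benjamini-Hochberg adjustment over 18 tests, 6 of them planned. Regions are not independent, and these tests compare the lines. A comparison of ranks was chosen after seeing the data: within each library, the fold of the 47767 regions present in all 6 libraries was turned into a percentile, so that every library ranks the same set. A region counts as above WT when all 4 mutated libraries have a higher percentile than both WT libraries. If all 6 libraries were exchangeable, 6.67% of regions would do so by chance. Across the genome 20.3% of the shared regions lay above WT and 20.1% below it. The rest of the chromosome, and not 6.67%, is therefore the reference used here.

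Named regions are all regions of the IgH subwindow, the line-specific regions of the IgH window, the 10 WT-only, mutated-only, CBE_1-only and CBE_2-only regions with the best significance rank in the library where they rank lowest, and the longest runs of missing regions. A run is at least 10 regions missing from 1 line that follow one another among the regions present in all 4 libraries of the other lines, so regions found in only some of those 4 may lie between them. Coordinates are 1-based positions of mm9. The gene table at hand is of another build, GRCm38.p6, so regions carry no gene names. Annotation classes, the fixed gene lists and a search for CTCF motifs, all planned, were not run.

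The merging and pattern counts were tested on simulated lists of 19994 regions, where the counts of the 6 patterns, 1219 regions in all, came back. Only counts per pattern were compared, not single regions. The simulated peaks lay well apart, had small shifts of their edges and were never missing from 1 library of a line. This checks the counting code and says nothing about errors in real lists, where peaks are closer and duplicates differ. Alternatives covered the significance threshold, the number of peaks per list, the overlap rule, the merging distance, the chromosomes used and each replicate left out. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. The 95% intervals for shares of peaks are Wilson intervals and cover counting error only.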

Results

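Open chromatin was mapped in 6 libraries from 3 mouse pro-B cell lines, 2 libraries per line. The WT line carries intact IGCR1, and CBE_1 and CBE_2 carry the mutated form. The WT lists held 112241 and 106056 peaks, those of CBE_1 72318 and 80242, and those of CBE_2 94665 and 97522. Peaks covered 80.1 and 75.4 Mb in WT, 52.6 and 59.6 Mb in CBE_1, and 69.0 and 70.1 Mb in CBE_2. On average WT had 1.43 times as many peaks as CBE_1 and 1.14 times as many as CBE_2. In each case every WT library had more peaks than every mutated library. Read depth behind the lists is unknown.

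The series asks how the mutation of IGCR1 alters the IgH locus, so that locus comes first. In the subwindow from the D, J and Cμ segments to the nearest VH segments, 2 regions were found in both WT libraries and in none of the 4 mutated libraries. They lie on chromosome 12 at 114723239 to 114724090, with deposited folds of 7.14 and 6.48 in the WT libraries, and at 114725829 to 114726376, with folds of 8.01 and 8.13. Their summits were 2.453 kb apart. They ranked at the 66.9th percentile or higher of their lists, and at least as strong WT-only regions numbered 540 for the weaker and 265 for the stronger of the pair across the genome. On the centromeric side, a region at 114719252 to 114721083 had folds of 7.47 and 6.92 in WT, 3.02 in CBE_1 replicate 1 and 2.82 and 2.79 in the CBE_2 libraries, and no peak in CBE_1 replicate 2. Between it and the pair, a region at 114721849 to 114722064 was found in WT replicate 2 alone, with a fold of 2.64. The narrow window set beforehand for IGCR1 held no peak in any of the 6 lists, and the pair lies on its centromeric side. The borders of this window are approximate and were not checked against an annotation. Its lack of peaks therefore does not show that IGCR1 is closed in WT, nor that the pair lies outside IGCR1. The share of WT-only regions in the subwindow, 2 of 24, did not differ from the rest of chromosome 12 (8.33% against 8.72%, two-sided Fisher exact p = 1). With the better 50% of each list the subwindow had 4 WT-only regions.

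**Figure D1:**
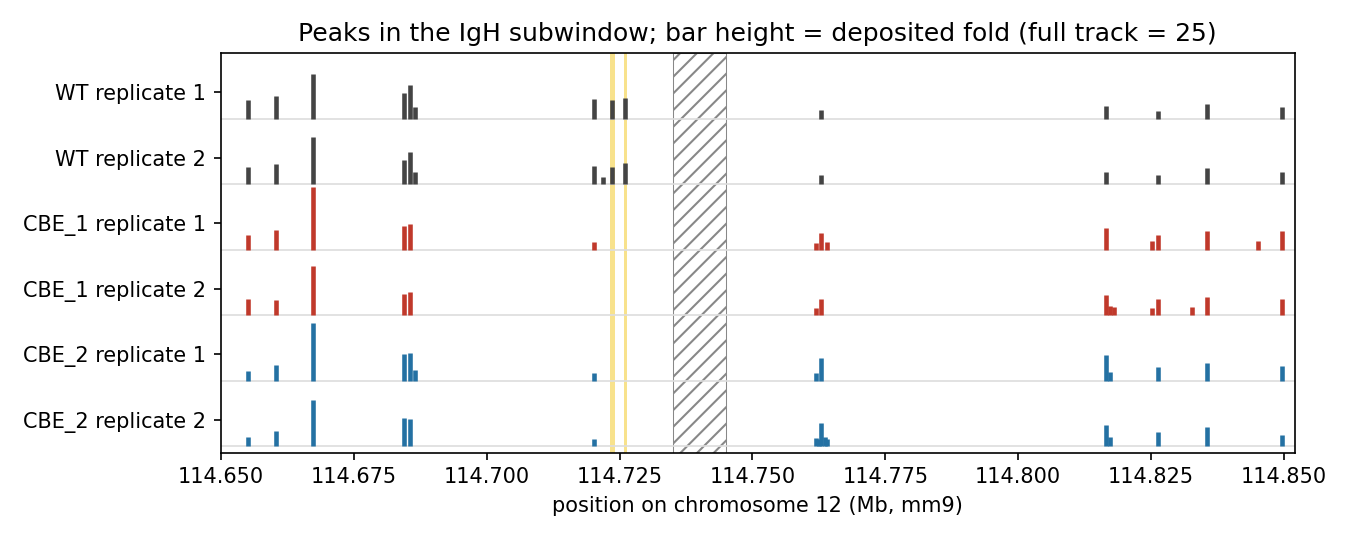
Peaks of each library in the IgH subwindow, against position on chromosome 12 in Mb of mm9; each bar stands at the middle of a region and its height is the deposited fold, on 1 scale for all libraries. The yellow bands mark the 2 WT-only regions, which have bars in both WT rows and in none of the 4 mutated rows. The hatched band is the window set beforehand for IGCR1, with no peak. Its borders are approximate and may miss IGCR1.

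Around the pair, 10 of the 24 regions were present in all 6 libraries. On the constant-region side these included 114664639 to 114670222 and 114684987 to 114686143, the nearest shared region to the pair on that side. On the VH side the nearest shared region, at 114762630 to 114763355, stood at percentiles 2.96 and 6.48 of the shared regions in WT, 48.5 and 46.1 in CBE_1, and 54.3 and 55.5 in CBE_2. A region near it, at 114761746 to 114762129, was present in all 4 mutated libraries and neither WT library, and between them 114762352 to 114762562 was found in CBE_2 replicate 2 alone. The region at 114816191 to 114816948 stood at 19.1 and 18.2 in WT, 59.1 and 56.7 in CBE_1, and 59.7 and 52.5 in CBE_2. At 114825856 to 114826672 the percentiles were 2.26 and 4.46 in WT, 43.9 and 45.3 in CBE_1, and 27.5 and 28.4 in CBE_2. At 114835184 to 114835818 they were 27.4 and 33.3 in WT, against 52.6 and 52.1 in CBE_1 and 41.6 and 46.3 in CBE_2. In the last shared region of the subwindow, at 114849154 to 114849934, CBE_1 was higher than WT in both libraries, at 54.3 and 45.3 against 13.1 and 15.8. There CBE_2 stood at 28.8 and 15.1, so its libraries fell on either side of WT replicate 2.

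**Figure D2:**
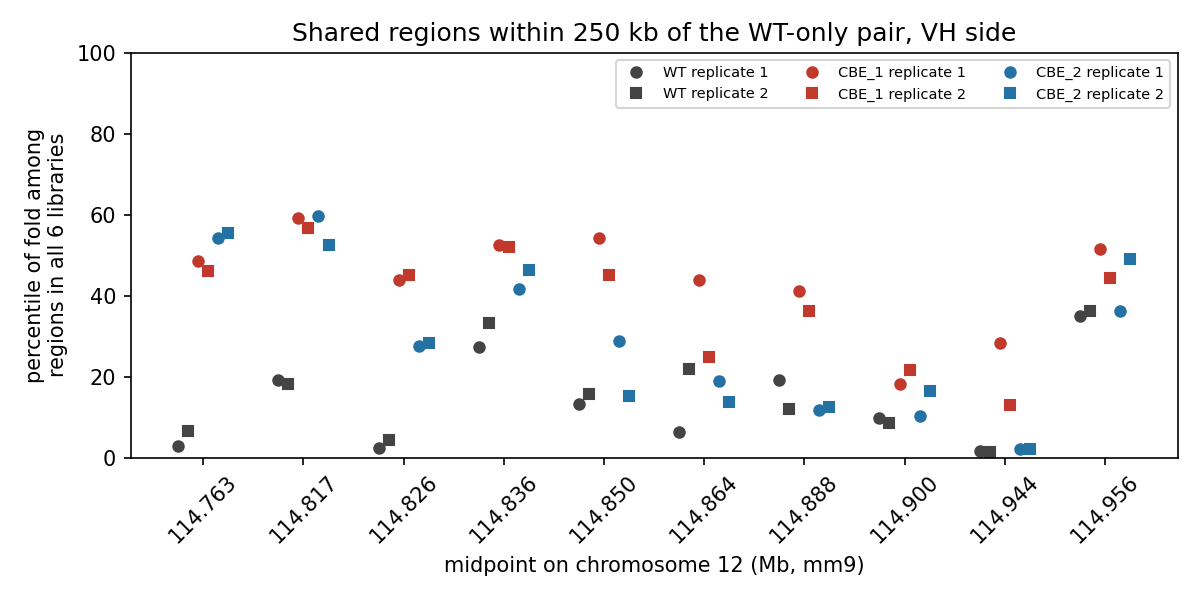
Percentile of the deposited fold among the regions present in all 6 libraries (vertical axis, 0 to 100) for the 10 shared regions within 250 kb of the pair on the VH side, ordered by their midpoint in Mb of mm9; each symbol is 1 library. In 6 of the 10 regions all 4 mutated libraries lie above both WT libraries.

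Over the whole VH side of the IgH window, 68 of 149 shared regions (45.6%) ranked higher in all 4 mutated libraries than in both WT libraries. The rest of chromosome 12 gave 21.0% (two-sided Fisher exact p = 1.79e-10), and 3.36% of VH-side regions ranked lower, against 21.4%. The median difference between the mutated and WT percentiles was 8.40 points on the VH side. Within 250 kb of the pair, a limit set after the values were seen and therefore not tested here, 6 of 10 regions ranked higher, with a median difference of 14.5 points. On the constant-region side 5 of 25 shared regions did so (20%, exact p = 1). One of these, at 114376706 to 114380251 and 343 kb from the pair, had the highest rise of the IgH window, from percentiles 1.65 and 5.45 in WT to 87.7 and 90.3 in CBE_1 and 72.0 and 70.0 in CBE_2. Across the genome 18 shared regions, this one included, rose by at least its 76.5 points, and 339 by at least the 46.4 points of the nearest VH-side region. By line, both CBE_1 libraries exceeded both WT libraries in 79.2% of VH-side regions and both CBE_2 libraries in 49.7%, against 34.1% for each line on the rest of chromosome 12. On the constant-region side both CBE_1 libraries were higher in 52% of regions and lower in 8%, and both CBE_2 libraries higher in 28% and lower in 44%. Differences between the mutated lines were not tested. In the 3 Mb on the centromeric side of the window 37.8% of 164 regions ranked higher (exact p = 3.17e-06), with a smaller median difference of 2.76 points. On the telomeric side 22.2% of 90 regions did (exact p = 0.791).

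Presence and absence in the IgH window showed few WT-only regions. Of its 386 regions, 7 were WT-only (1.81%, against 9.21% of the rest of chromosome 12; two-sided Fisher exact adjusted p = 1.93e-07). The other 5, with folds of 2.70 to 4.22, were weaker than the pair. Of the window's regions 45.1% were present in all 6 libraries, against 33.1% on the rest of chromosome 12. This leaves a smaller share for patterns of absence. The count of 7 was 15 without WT replicate 1, 13 without WT replicate 2, and 4 with lists of the same length. Mutated-only regions numbered 8 (2.07% against 1.57%; exact test, adjusted p = 0.558), all on the VH side, which holds 322 of the 386 regions, and with folds of 2.25 to 4.41. CBE_1-only regions numbered 16 (4.15% against 0.622%; exact test, adjusted p = 5.28e-07), 14 of them on the VH side. CBE_2-only regions numbered 3 (0.777% against 3.00%; exact test, adjusted p = 0.0198). CBE_1-absent regions numbered 3 (0.777% against 6.00%, exact test, adjusted p = 3.01e-06), and CBE_2-absent regions 1 (0.259% against 0.421%). IgH peaks made up 0.229% (Wilson interval 0.203 to 0.259) and 0.245% (0.217 to 0.277) of the WT lists. They made up 0.422% (0.377 to 0.472) and 0.424% (0.381 to 0.471) in CBE_1, and 0.295% (0.262 to 0.331) and 0.298% (0.266 to 0.335) in CBE_2. The WT-only odds ratio of 0.182 stayed below 1 in all alternatives, but among strong regions alone, those in the better 50% of every list that held them and absent elsewhere at any threshold, it was 0.364 with exact p = 0.173, on 2 regions. The mutated-only odds ratio of 1.32 passed 0.05 (exact p = 0.0265 to 0.0376) without WT replicate 1, WT replicate 2, CBE_1 replicate 1 or CBE_2 replicate 1, where the count rose to between 13 and 16. It turned below 1 with the better 50% of each list (0.703, exact p = 0.796), with lists of the same length (0.929, exact p = 1) and among strong regions (0, exact p = 0.167).

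The Igk light chain locus, which was not mutated, moved in the same direction. Its window held 258 regions, of which 6 were WT-only (2.33%, against 7.39% of the rest of chromosome 6; two-sided Fisher exact adjusted p = 0.00304). Mutated-only regions numbered 10 (3.88% against 1.78%; exact test, unadjusted p = 0.0283, adjusted p = 0.0638). CBE_1-only regions numbered 5 (1.94% against 0.463%, exact test, adjusted p = 0.0245) and CBE_1-absent regions 1 (0.388% against 6.03%, adjusted p = 2.13e-05). CBE_2-only regions numbered 5 (1.94% against 3.48%, exact test, adjusted p = 0.402) and CBE_2-absent regions 2 (0.775% against 0.425%, adjusted p = 0.484). Here too more regions were present in all 6 libraries, 53.1% against 30.0% on the rest of chromosome 6. Of 137 shared regions 37.2% ranked higher in all 4 mutated libraries than in both WT libraries, against 21.4% on the rest of the chromosome (exact p = 4.86e-05), with a median difference of 5.96 points. By line, both CBE_1 libraries exceeded both WT libraries in 67.2% of regions, against 32.9% on the rest of the chromosome, and both CBE_2 libraries in 43.8%, against 38.4%. With only the better 50% of each list, 31.3% of Igk regions ranked higher (exact p = 0.0503), and among strong regions the odds ratios at Igk were 0.773 for WT-only and 0.687 for mutated-only regions (both exact p = 1).

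Across the genome the peaks merged into 149724 regions, of which 47767 (31.9%) were present in all 6 libraries and 41841 in 1 library. Regions found only in WT numbered 13003, and those found only in the mutated lines 2272, a ratio of 5.72. The 2 counts follow unlike rules, presence in 2 lists against presence in all 4, so the ratio does not measure a net loss. The same 2 counts were 4701 and 977 for the CBE_2 libraries, and 998 and 7567 for those of CBE_1. Pairs from different lines also varied, with 1200 and 50 for WT replicate 1 with CBE_2 replicate 2. WT replicate 2 with CBE_1 replicate 1 had 278 and 502. Without WT replicate 1 or WT replicate 2, WT-only regions numbered 22812 and 27356, and without WT replicate 2 the ratio was 10.04. Without the CBE_1 line mutated-only regions numbered 8548 and the ratio was 1.87. Every pair of libraries from 2 different lines had between 204 and 1200 regions of its own. The WT pair had the highest count of the 15 possible pairs. For regions missing from a pair and present in the other 4 libraries, CBE_1 came first with 7567, followed by WT with 2272 and CBE_2 with 977. CBE_1-only regions numbered 998 and CBE_2-only regions 4701. The CBE_1 count lies within the range of 204 to 1200 for pairs from 2 different lines, and the CBE_2 count lies above it. Leaving out 1 library of the line raised CBE_1-only regions to 4844 (without replicate 1) and 4829 (without replicate 2), and CBE_2-only regions to 11534 and 10805. CBE_1-absent regions numbered 13255 without CBE_1 replicate 2, and CBE_2-absent regions 2359 without CBE_1 replicate 1, 1548 without CBE_1 replicate 2 and 1658 without CBE_2 replicate 2. With the same number of peaks from each list, WT-only regions fell to 6445 and CBE_1-absent regions to 3394, mutated-only regions were 3093 and CBE_1-only regions 2192, and the ratio was 2.08. Counting only strong regions left 1936 WT-only and 633 mutated-only regions.

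**Figure D3:**
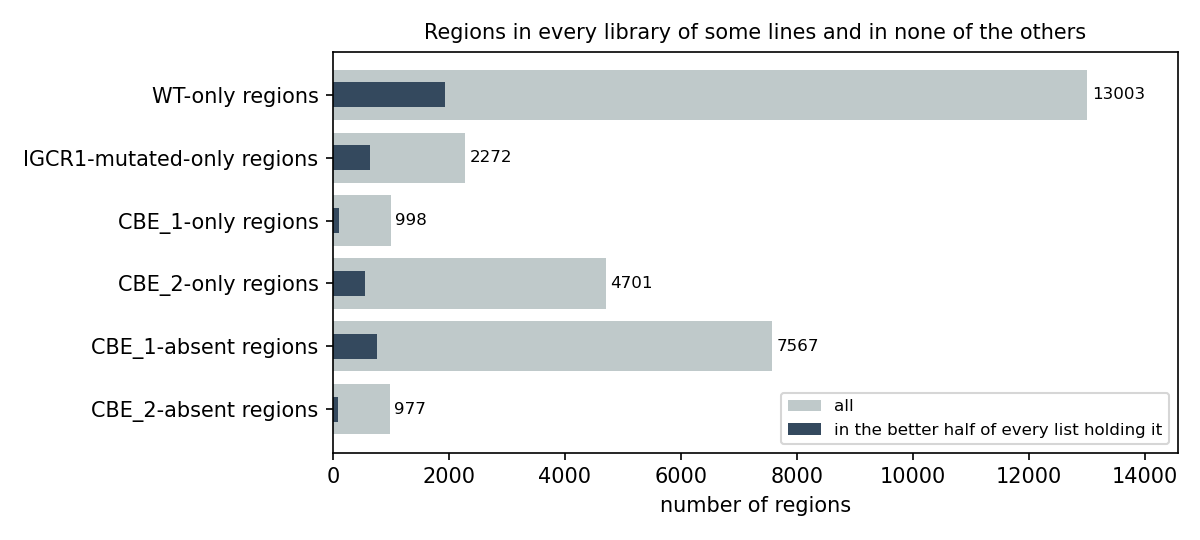
Number of regions (horizontal axis) present in both libraries of the named line or lines and in none of the others, or absent from 1 line and present in the other 4 libraries; the narrow dark bars count those in the better 50% of every list that holds them. WT-only regions, 13003 in all and 1936 among the strong ones, are the most numerous of the 6 kinds.

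The WT-only regions with the best ranks included chromosome 9 at 29423644 to 29425317, with folds of 22.4 and 22.7, chromosome 10 at 126109401 to 126111588, with folds of 22.3 and 23.3, and chromosome 2 at 173546809 to 173548983, with folds of 20.8 and 21.2. Of the 10 named, 3 lay on chromosome 10, and the weakest had a fold of 16.5. The mutated-only regions were led by chromosome 1 at 82278857 to 82280908, with folds of 23.3 to 28.8, and a second of the 10 lay 4.88 kb away at 82285786 to 82290060. Next came chromosome 19 at 44340615 to 44342391 and chromosome 11 at 120049969 to 120052387. Of the regions found in a single mutated line, the first CBE_1-only region, on chromosome 12 at 72931307 to 72933193, had folds of 17.8 and 22.0, and the lowest fold among its 10 was 9.17. The first CBE_2-only region, on chromosome 5 at 21866228 to 21867273, had folds of 18.04 and 18.64, and the lowest among its 10 was 13.4. Without an annotation of the same build, the genes at these positions are not given here.

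Libraries of 1 line shared more of their covered bases than libraries of different lines. The share of overlapping peaks did not always follow this. Of the CBE_1 replicate 2 peaks, 75.6% overlapped a peak of CBE_1 replicate 1, but 84.5% and 83.1% overlapped the longer WT lists. The Jaccard index of covered bases was 0.752 between the WT libraries, 0.717 between those of CBE_1 and 0.765 between those of CBE_2. Between lines it averaged 0.637 for CBE_1 with CBE_2, 0.611 for WT with CBE_2 and 0.562 for WT with CBE_1. Of the 15 ways to pair the 6 libraries the real one had the highest mean, 0.745 against 0.676 for the next (exact permutation p = 0.0667, one-sided, the smallest this design allows).

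Single chromosomes differed between the lines. Chromosome 18 held 5.37% and 5.20% of the WT peaks, 5.68% and 5.97% of the CBE_1 peaks, and 3.12% in both CBE_2 libraries. Chromosome 19 held 3.79% and 3.75% in WT, 2.79% and 2.70% in CBE_1, and 2.47% in both CBE_2 libraries. WT-only regions made up 20.6% of all regions on chromosome 19, against 8.28% elsewhere (two-sided Fisher exact adjusted p = 2.74e-150 over 120 tests), and the next chromosome, 10, had 12.1%. The odds ratio of 2.88 was 1.89 among strong regions (exact p = 1.21e-09). CBE_2-absent regions made up 3.10% of chromosome 18, against 0.505% elsewhere (exact test, adjusted p = 4.32e-101), but among strong regions the odds ratio fell from 6.31 to 1.59 (exact p = 0.223). Chromosome 11 went the other way, with 5.27% and 5.34% of the peaks in WT, 7.14% and 6.72% in CBE_1, and 6.12% and 6.16% in CBE_2. Its WT-only share was the lowest of all chromosomes, 5.04% against 8.89% elsewhere (odds ratio 0.544, exact test, adjusted p = 6.25e-36), and its mutated-only share the highest, 2.53% against 1.46% (odds ratio 1.75, exact test, adjusted p = 3.20e-11). Without chromosomes 10, 18 and 19, WT-only regions numbered 9905 and mutated-only regions 2036.

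**Figure D4:**
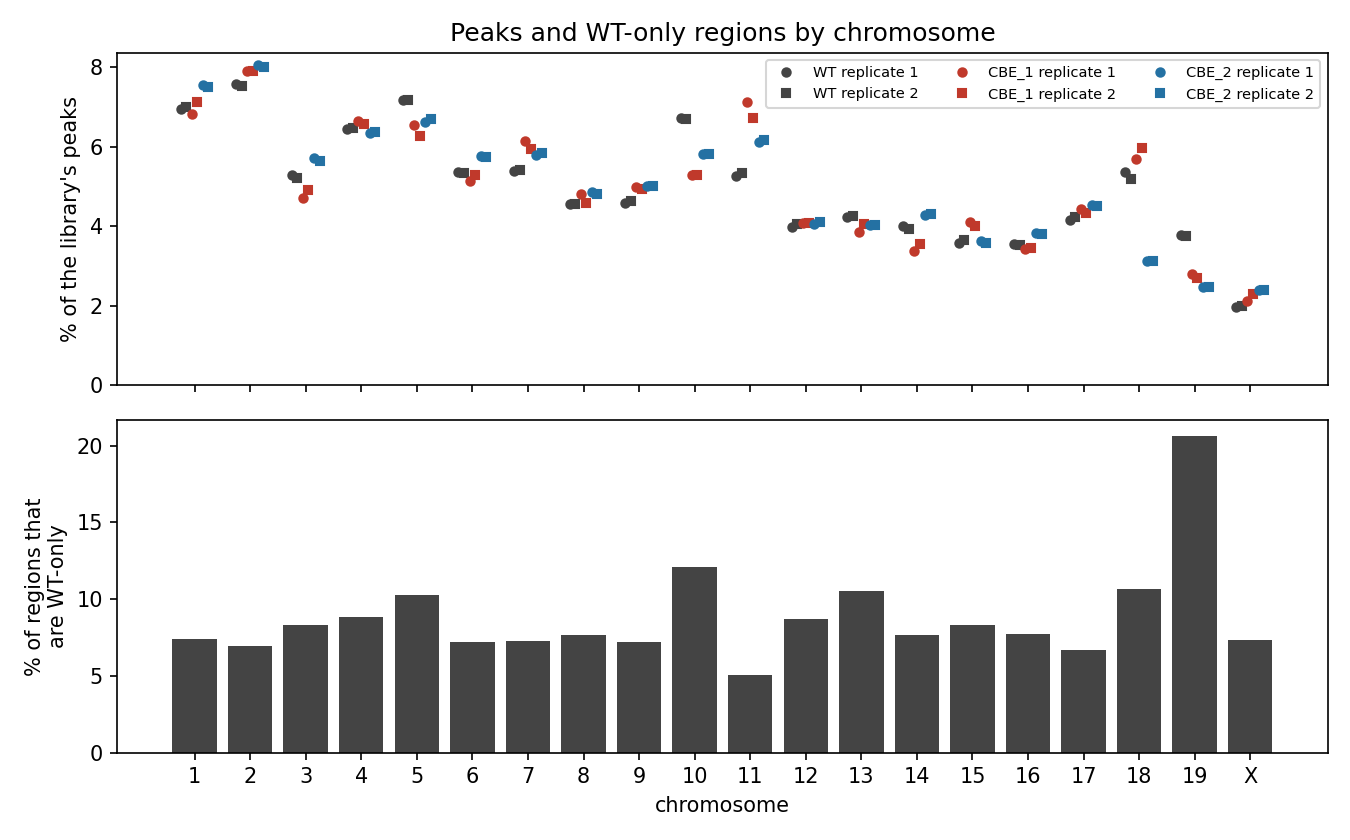
Upper panel, percent of each library's peaks on each chromosome, 1 symbol per library; lower panel, percent of the regions of each chromosome that are WT-only. Chromosome 18 is low in both CBE_2 libraries at 3.12%, and chromosome 19 has the highest WT-only share at 20.6%.

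Among the regions present in all 4 libraries of the other lines, at least 10 in a row were missing from both CBE_1 libraries at 4 places, and no such run was found for WT or CBE_2. Regions found in only some libraries lie between them. The longest in regions, on chromosome 10 at 48768946 to 50032298, spanned 19 such regions over 1263 kb and held no peak in either CBE_1 library, 38 and 37 in WT, and 26 and 27 in CBE_2. On chromosome 6, from 113912772 to 114027007, 16 regions over 114.2 kb were missing, with no peak in CBE_1, 19 and 20 in WT, and 23 and 27 in CBE_2. The others lay on chromosome 10 at 8732725 to 9619406, with 11 regions and 1 peak in each CBE_1 library, and on chromosome 14 at 60225897 to 60607540, with 10 regions and 1 peak in CBE_1 replicate 2. With lists of the same length there were 2 runs in CBE_1 and 1 in WT, without CBE_1 replicate 2 there were 7 in CBE_1, and without WT replicate 2 there was 1 in WT.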

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

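The choice of results compared between the mutated lines, and the tests in this part except the count of similar pairs, were chosen after the values had been seen. In 32 results, namely the share of peaks on each chromosome and in each locus and the ranks of the shared regions of the IgH subwindow, 7 had both CBE_1 libraries on one side of both WT libraries and both CBE_2 libraries on the other. If all 6 libraries were exchangeable, chance would give 0.711 such results, or 2.22%. Duplicates of a line are more alike than libraries of different lines, so lines that merely differ would give more. Shares of 1 library also depend on one another. The 7 results are therefore no measure of an excess over chance. The differences between the lines were not tested.

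The share of peaks on chromosome 18 was 2.71 percentage points higher in CBE_1 than in CBE_2, with WT between them. The same order held for chromosome 4, at 0.252 points. The reverse order, CBE_1 lowest and CBE_2 highest, held for chromosome 3, where the difference of CBE_1 minus CBE_2 was -0.872 points, chromosome 14 at -0.830, chromosome 6 at -0.552 and chromosome 16 at -0.380. In the IgH subwindow, the region on chromosome 12 at 114653882 to 114656527 ranked 35.7 percentile points higher in CBE_1 than in CBE_2, with means of 42.7 and 7.03 against 38.8 in WT.

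The pair of WT-only regions in the IgH subwindow was set against lower sensitivity of the mutated lists and against differences between lines. Of 31631 regions at least as strong as the weaker of the pair in both WT lists, 1.71% were absent from all 4 mutated lists. This set has no upper limit of strength, and weaker detection would seldom remove its strongest peaks. Regions of about the pair's own strength were not looked at alone, so the share cannot decide on weaker detection as the cause. Elsewhere in the genome 22 neighbouring pairs of WT-only regions within 5 kb were as strong, so a difference between lines unrelated to the mutation and an effect of the mutation cannot be told apart with 1 WT line. As a hypothesis, the pair may be the CTCF elements that were mutated in these lines; no sequence of the same build was at hand to test this. A changed sequence that keeps reads from mapping also stays open.

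The higher ranks on the VH side in the mutated lines exceed what regions of the same mean rank show: 45.6% of regions against at most 31.5% in 10000 draws (permutation p = 0.0001, the smallest they can give). A gain of the end of chromosome 12 would also raise the telomeric flank, which stood lower (22.2%, two-sided Fisher exact p = 0.000301 against the VH side), although the centromeric flank stood higher than the rest of the chromosome at 37.8%. Igk also rose against the rest of chromosome 6 (two-sided Fisher exact p = 4.86e-05, and 0.0503 with the better 50% of each list). This cannot exclude an effect of the mutation at IgH, because both can occur together. Both CBE_2 libraries exceeded WT in 43.8% of Igk regions, against 38.4% on the rest of chromosome 6. On the VH side they did so in 49.7%, against 34.1% on the rest of chromosome 12. For CBE_1 the shares were 67.2% against 32.9% and 79.2% against 34.1%. Distance from the pair did not order the gains over all 149 regions. Spearman rho was -0.00385 in CBE_1 (permutation p = 0.962) and -0.14 in CBE_2 (permutation p = 0.0852). The 10 regions within 250 kb were picked after their gains were seen, so neither their fall with distance (rho = -0.89 in CBE_1 and -0.818 in CBE_2) nor their comparison with regions of the same mean rank (permutation p = 0.0013) decides anything, and the highest rise of the window, 76.5 points, lay on the other side of the pair. An effect of the mutation on nearby VH regions and differences between the 3 lines in stage or culture stay open.

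Line-specific regions were concentrated on single chromosomes, with 20.6% of chromosome 19 regions WT-only. Fewer peaks in the mutated lists are argued against as the whole cause, since with the same number of peaks from each list WT-only regions on chromosome 19 kept an odds ratio of 2.51 (two-sided Fisher exact p = 1.37e-52), against 2.88 with the full lists, 2.15 with the better 50% of each list and 1.89 among strong regions (exact p = 1.21e-09). More copies of chromosome 19 in the WT line would raise it throughout. In all 7 of its 10 Mb segments the shared regions had a higher median rank in both WT libraries than in all 4 mutated libraries. The same held in 16.5% of 249 segments of other chromosomes. The margin to CBE_1 was small in places. In the segment from 0 Mb, WT replicate 2 stood at 67.36 and CBE_1 replicate 1 at 67.25. From 20 Mb they stood at 56.97 and 55.91. A difference in chromosome number between cultured lines is therefore a hypothesis only, with uneven margins along the chromosome. For chromosome 18 in CBE_2, 7 of 9 segments were lower than in the other 4 libraries, against 7.23% of segments elsewhere. The first 2 segments were not, and from 20 Mb the margin was small, 38.45 in CBE_2 replicate 1 against 38.97 in WT replicate 2. A loss of the whole chromosome stays undecided.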

How the results depend on the processing

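The alternatives that required 50% coverage by peaks, looked at strong regions alone, left out chromosomes 10, 18 and 19 or the CBE_1 line, or changed the rank column or reference were chosen after seeing the data. Of the summary results under all alternatives, 341 values kept their direction and side of the threshold or stayed within the allowed range, 60 moved beyond it, 7 fell below and 4 rose above the test's threshold, and 4 turned direction. The 10 best-ranked regions of each kind and the IgH pair rank too high in their lists for shorter lists to change their pattern. A left-out replicate cannot change it either, because the pattern by definition holds in every library that remains. These settings therefore say nothing about their stability. The planned rule that a peak cover 50% of a region or lie 50% inside it moves nothing for merged regions. Neither does the restriction to chromosomes 1 to 19 and X. Values of these settings are among the 341, as are ratios of peak numbers that lists of the same length fix. The count of 341 therefore overstates stability. Ranks by the deposited −log10 q-value gave the same 45.6% on the VH side and 37.2% at Igk, with 21.2% on the rest of chromosome 12, but both columns follow from the same counts. Other settings for annotation classes, gene lists and CTCF motifs were not run. No paired analysis was possible because replicate numbers follow accession order only. The rank result of the VH side held under each alternative run for it, at 40.9% to 57.0%, the highest without CBE_2 replicate 2. The share on the rest of chromosome 12 changes between settings too, and with fewer libraries the rule is easier to meet. A higher percent is therefore not in itself a stronger result.

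With the better 50% of each list, counts fell because fewer peaks entered: WT-only 7660, mutated-only 1331, CBE_1-only 396, CBE_2-only 2366, CBE_1-absent 4396 and CBE_2-absent 440 regions. In the IgH window the mutated-only odds ratio turned to 0.703 (exact p = 0.796) on 3 regions, and the subwindow had 4 WT-only regions. At Igk 31.3% of regions ranked higher (exact p = 0.0503), and near the pair, in the set picked after the values were seen, 66.7% of fewer regions. WT had 1 missing run and CBE_1 2, and the Jaccard indices were 0.813 within and 0.649 between lines.

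With the same number of peaks from each list, WT-only regions were 6445, CBE_1-only 2192 and CBE_1-absent 3394, and the ratio of WT-only to mutated-only was 2.08, so list length sets much of these counts. IgH had 4 WT-only regions and a mutated-only odds ratio of 0.929 (exact p = 1). WT had 1 missing run and CBE_1 2, and the Jaccard indices were 0.781 and 0.641. With summits, CBE_1-only regions were 1610 and the Igk mutated-only odds ratio was 1.74 (exact p = 0.115). With peaks up to 500 bp apart merged, IgH had 4 WT-only and 5 mutated-only regions, and the Igk mutated-only odds ratio was 2.11 (exact p = 0.0632). Requiring 50% coverage gave 3 missing runs in WT. Requiring 50% of both peaks, an average of 75.3% of peaks were shared within lines (83.3% at 1 bp) and 60.2% between lines (72.9%).

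Strong regions alone numbered 1936 WT-only, 633 mutated-only, 112 CBE_1-only, 544 CBE_2-only, 762 CBE_1-absent and 80 CBE_2-absent, with a ratio of 3.06. Odds ratios were 0.364 (exact p = 0.173) for the 2 WT-only and 0 (p = 0.167) for the 0 mutated-only regions of IgH, 0.773 and 0.687 (both p = 1) for Igk, 1.59 for CBE_2-absent regions on chromosome 18 and 1.89 for WT-only regions on chromosome 19. Without chromosomes 10, 18 and 19, CBE_2-absent regions were 646. Without the CBE_1 line, mutated-only regions were 8548, the ratio was 1.87, and IgH had 11 WT-only and 21 mutated-only regions; fewer libraries had to agree. Apart from those whose construction is named, the cause of these changes was not tested.

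Leaving out each replicate in turn lets 1 library stand for its line, which raises counts. WT-only regions ranged from 13576 to 27356 (without WT replicate 2), the ratio from 4.15 to 10.04, CBE_1-only from 1171 to 4844, CBE_2-only from 5201 to 11534, CBE_1-absent from 8543 to 13255 (without CBE_1 replicate 2) and CBE_2-absent from 1166 to 2359. In IgH, WT-only regions ranged from 7 to 15, mutated-only regions from 9 to 16 and their odds ratio from 1.26 to 1.96. Missing runs ranged from 0 to 1 in WT and from 4 to 7 in CBE_1. The lists hold no read depth, only the inferred background counts, so how far depth limits the counts of absence was not measured. By that count CBE_1 replicate 2 had the highest background of the 6 libraries, 8.59, but 80242 peaks. The WT libraries had 112241 and 106056 peaks at backgrounds of 8.24 and 8.10. A low background thus does not go with the short list of CBE_1 replicate 2, but this rests on 1 library and decides nothing for the line.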
